A study of Mus musculus with 18 samples.

How the data were processed

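Bulk RNA was measured in 18 mouse libraries in 6 groups of 3: fibroblasts, iECs and native ECs from heart and lung, all at day 7. Per the labels, cells were kept in EGM2, RNA was taken with a column kit and mRNA libraries were sequenced by a service company. The authors' processing notes name Salmon, DESeq2 and the mm10 build, with no versions and no statement of how transcripts were summed to genes. The deposited table holds expected_counts, that is, estimated counts per gene, in whole numbers with 0 values that are not whole and with no scaling of library totals. It lists 35727 gene IDs, of which 35422 had a symbol in the annotation used (GENCODE release M21 on GRCm38) and 13349 had no count in any library. The 305 IDs without a symbol held 0.0532% of the counts. Every column could be assigned to a sample from its name and the labels.

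Totals per library ranged from 17747632 to 23775372 estimated counts, and 15928 to 17291 genes had a count. A floor of 3 counts over the 3 libraries of a group stands in for 0 where a fold is given as a lower bound, which for the groups without a count equals 0.0434 to 0.0549 CPM. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Pearson's r of log2 CPM between replicates ranged from 0.975 to 0.9894. The spread between replicates over genes with at least 20 counts was 4.52 to 68.7 times that of counting error (chi-squared per degree of freedom). The first 3 principal components held 37%, 24.2% and 17.4% of the variance.

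Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 6 groups (14864 genes, 99.97% of counts), scaled by TMM and fitted with robust quasi-likelihood models over all 18 libraries with 1 coefficient per group, leaving 12 residual degrees of freedom and a common biological coefficient of variation of 0.135. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, within each contrast. The contrasts were iEC against fibroblast, EC against fibroblast and iEC against EC in each organ, lung against heart in each cell type, the difference of the iEC response between organs, and the difference of the lung to heart change between iECs and ECs. The absolute log2 change divided by the square root of its quasi-likelihood F statistic served as its SE, given after ±. Such an SE can understate the error of a large change where a group has few counts. CPM values are group means.

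Before the data were examined, 32 gene lists with 429 unique genes were written, of which 390 were tested and 31 lists had at least 3 tested members. They cover endothelial subtypes and transcription factors, organ mesenchyme factors, fibroblast, contractile, cell cycle and signalling genes, and markers of cells that a culture could carry. Lists were tested with fry in limma 3.58.1, with camera under an estimated correlation and under a preset correlation of 0.01 as alternatives. Camera asks whether a list stands apart from the other genes, so it is not a correction of fry. P-values marked with an estimated correlation come from camera. The comparisons, tests, alternatives and rule for naming genes were set at the same time. The rule names Sox17 and Erg. It names the 6 genes with the largest change in each direction of each contrast, among called genes with at least 10 CPM in the higher group and groups that do not overlap, without clone, pseudogene and predicted gene symbols. It names up to 4 called members of a described list with at least 5 CPM and 1 called in the opposite direction. It names the 6 genes per direction gained and 4 shared between organs, and other list members may be given as values. Of the genes the rule names, those that lost their call when 1 library was left out are not described. Gene IDs and positions are given for Sox17 and Erg.

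The position of a library was its projection on the axis between the fibroblast and EC means of log2 CPM (prior count 2), over genes called with at least 2-fold between them. Organ overlaps were counted over called genes and set against the number that independent lists would share. Correlations were computed across genes. Exact permutation tests used all 10 splits of 6 libraries. Wider marker lists of macrophage and leukocyte (235 genes), mesothelial and epicardial (43) and epithelial (69) genes were compiled after the data were seen and tested with Fisher's exact test, with 222, 41 and 49 genes tested.

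Alternatives were DESeq2 1.42.0, RLE scaling, no filter beyond 1 count, at least 5 CPM in at least 3 libraries, fits to the compared groups alone, a block for the replicate number, a test against a log2 change of 1 (glmTreat), prior counts of 5 and 0.5, other gene sets for the position and correlations, and each library left out. Those without the wider marker lists, and the position over genes shared by both organs, were chosen after the data were seen. The fits were tested on simulated data made from the real libraries: 41 of 67 genes changed 1.5-fold, 62 of 67 changed 2-fold and 61 of 66 changed 4-fold were recovered, 7 of 171 calls were false, a position made at 0.4 was recovered at 0.4, and 0 of 30 unchanged lists were called. In the simulated comparison of heart iECs with heart fibroblasts few genes were changed and genes were drawn independently, whereas the real comparison called 7530 genes. The simulation thus does not test scaling, or false calls of lists, where about that many genes differ and genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.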

Results

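RNA was measured by sequencing of polyadenylated transcripts in 18 libraries of cultured mouse cells, all taken at day 7. The labels give 6 groups of 3 libraries: control fibroblasts, native endothelial cells (ECs) and iECs, each from heart and from lung. The labels do not spell out iEC, which in this field stands for endothelial-like cells induced from another cell type. Titles of the iEC libraries read SEG in place of iEC, a term the labels do not explain. All cultures were kept in EGM2, a medium made for endothelial cells. The stated purpose of the series was to ask whether iECs take on endothelial features of the organ they come from. Totals ranged from 17747632 to 23775372 estimated counts per library, so that 1 count in the shallowest library equals 0.0563 CPM (counts scaled to the library total). Of the 14864 genes tested, between 37.7% and 58.1% differed in each comparison of a pair of groups. The root mean square log2 distance between libraries averaged 0.524 within groups. It was 1.23 between heart iECs and heart fibroblasts, 1.24 between heart iECs and heart ECs, 1.28 between lung iECs and lung fibroblasts and 1.21 between lung iECs and lung ECs. Heart ECs stood 1.04 from heart fibroblasts, the smallest distance between any pair of groups, and lung ECs 1.46 from lung fibroblasts. Heart and lung iECs stood 1.11 apart, closer to each other than either stood to the fibroblasts or ECs of its own organ.

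Sox17 and Erg, transcription factors that mark the endothelium, were far above native levels in both kinds of iECs. Sox17 (ENSMUSG00000025902; chromosome 1, 4490931 to 4497354 on the minus strand of GRCm38) stood at 466 ± 29.2 CPM in heart iECs and 475 ± 75.8 CPM in lung iECs (SD), against 6.81 in heart ECs, 14.2 in lung ECs, 1.37 in heart fibroblasts and 0.126 in lung fibroblasts (means, n = 3 each). Erg (ENSMUSG00000040732; chromosome 16, 95359169 to 95586593, minus strand) stood at 1024 ± 47.2 CPM in heart iECs and 1034 ± 133 CPM in lung iECs, against 51.5 in heart ECs, 85.5 in lung ECs, 8.25 in heart fibroblasts and 0.544 in lung fibroblasts. On the log2 scale Sox17 rose by 8.40 ± 0.188 (SE) in heart iECs over fibroblasts and by 11.75 ± 0.240 in lung iECs, and Erg by 6.96 ± 0.210 and 10.84 ± 0.268 (edgeR adjusted p = 7.14e-16, 1.51e-16, 7.62e-14 and 7.26e-15). Both genes are protein coding. The table gives 1 value per gene, whatever copy its transcripts come from.

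**Figure D1:**
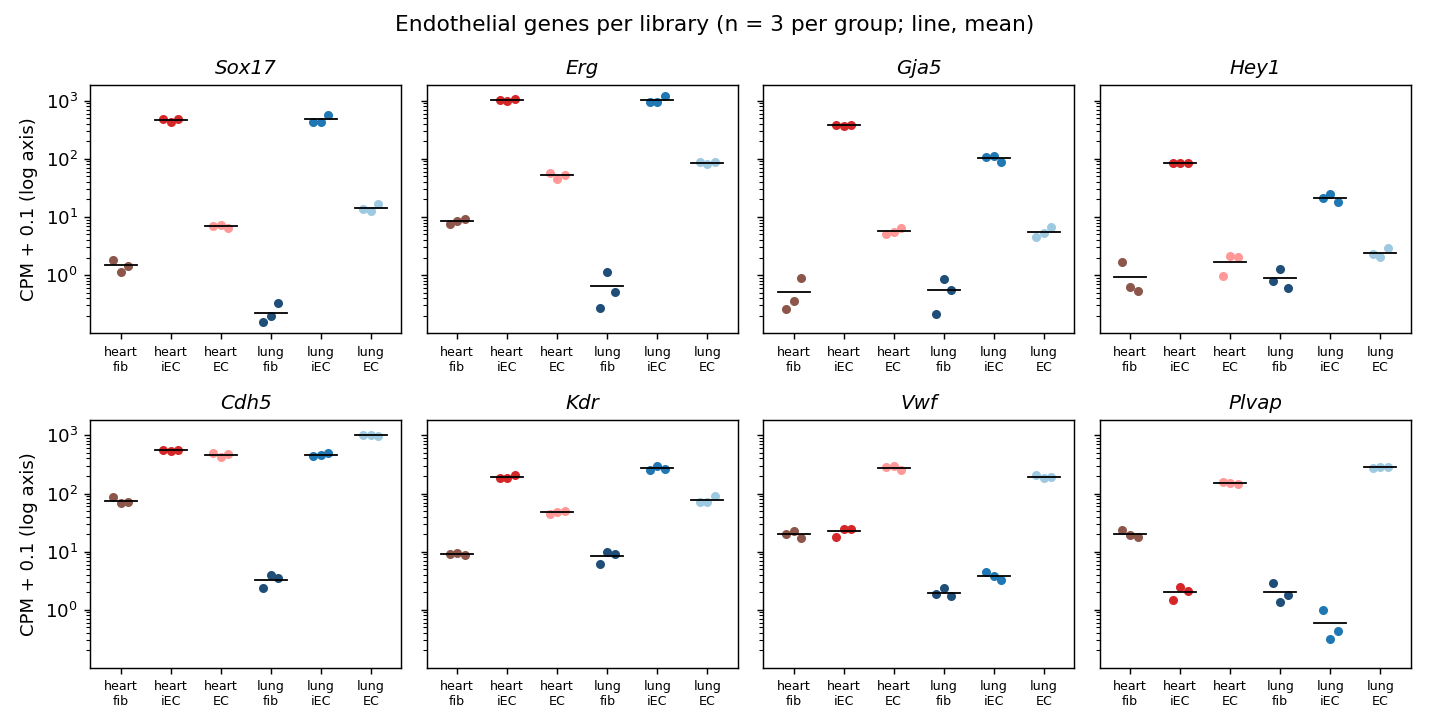
CPM plus 0.1 on a log axis for 8 endothelial genes in each library, with 3 libraries per group and a line at the group mean. Sox17 and Erg peak in iECs at about 466 to 475 and 1024 to 1034 CPM, Cdh5 reaches 555 CPM in heart iECs and 465 CPM in lung iECs, and Vwf and Plvap stay below their native EC levels in all 6 iEC libraries.

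Heart iECs differed from heart fibroblasts in arterial genes. Of 19 tested members of the arterial list 16 rose and 3 fell. Both fry and camera, which sets a list against the other genes, called it (fry adjusted p = 2.41e-13, camera adjusted p = 0.00524 with an estimated correlation). Gja5, the gap junction gene of arterial endothelium, rose by 9.90 ± 0.302, the Notch target Hey1 by 6.62 ± 0.325 and Sema3g by 5.49 ± 0.202, while Vegfc fell by 0.70 ± 0.129. Of 16 Notch pathway genes 9 rose, among them Heyl by 4.02 ± 0.323 and the ligand Dll4 by 3.70 ± 0.144, and 2 fell (adjusted p = 0.245 with an estimated correlation). Of 28 pan-endothelial genes 16 rose and 9 fell. The VEGF receptor gene Kdr rose by 4.43 ± 0.142, S1pr1 by 4.06 ± 0.144 and Icam2 by 3.38 ± 0.181, whereas Nos3, the endothelial nitric oxide synthase, fell by 3.39 ± 0.346 (adjusted p = 0.274 for the list with an estimated correlation). Endothelial transcription factors were split, with 10 rising and 8 falling of 24 tested, a median of 0.04 and a mean of 1.08 (adjusted p = 0.402 with an estimated correlation). Sox17 and Erg belong to this list and raise its mean, and Sox17 belongs to the arterial list too. No list was tested without them.

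Fibroblast and matrix genes fell in 17 of 30 cases in heart iECs, among them the dermatopontin gene Dpt at −5.01 ± 0.112, Lum at −4.91 ± 0.309 and Dcn at −3.57 ± 0.363, while 5 rose, with Mfap5 at 1.09 ± 0.0977 (adjusted p = 0.315 with an estimated correlation). Contractile genes moved the other way: 11 of 15 rose and none fell, among them the smooth muscle genes Tagln by 3.11 ± 0.149 and Acta2 by 2.22 ± 0.186 (adjusted p = 0.402 with an estimated correlation). Cell cycle genes rose in 18 of 20 cases, for example Cdc20 by 3.24 ± 0.152 and Mki67 by 2.87 ± 0.177 (adjusted p = 0.274 with an estimated correlation). Of 18 TGF-beta and BMP genes 10 rose, with Bmp4 at 2.55 ± 0.101, and 3 fell (adjusted p = 0.142 with an estimated correlation). Of 16 interferon genes 8 fell and none rose, with Ifit3 at −2.91 ± 0.648 (fry adjusted p = 0.0411, adjusted p = 0.789 with an estimated correlation). A block for the replicate number ended this call of the interferon list. Mesothelial genes included Msln, which fell by 5.30 ± 0.291, and Gpm6a, which rose by 3.99 ± 0.171; with 2 rising and 7 falling of 10, this list was not called (fry adjusted p = 0.266), while a wider set of 41 tested mesothelial and epicardial genes went from 1.10% ± 0.0596 of counts in heart fibroblasts to 0.105% ± 0.00467 in heart iECs (SD, n = 3). The macrophage list was not called either (5 rose and 2 fell of 16; fry adjusted p = 0.136; median 0.28, mean −0.02), and a wider set of 222 tested macrophage and leukocyte genes went from 0.703% ± 0.0200 of counts to 0.270% ± 0.00638. Tmprss5 and Lpo had no count in heart fibroblasts and stood at 28.3 and 11.2 CPM in heart iECs, at least 516-fold and 204-fold higher against a floor of 3 counts over the group. The largest declines included Eef1a2 (−8.47 ± 0.450), the haptoglobin gene Hp (−8.08 ± 1.04) and Serpina3m (−6.93 ± 0.240).

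In all, 3868 genes were higher and 3662 lower in heart iECs than in heart fibroblasts by edgeR's quasi-likelihood test at an adjusted p threshold of 0.05. Fry asks whether the genes of a list move, on balance, in one direction and does not set the list against other genes, so a called list can hold members of both signs. Camera, the source of each p-value given with an estimated correlation, does set the list against the other genes. Adjusted over the list alone, the counts were the same for each list named for heart iECs against heart fibroblasts except the endothelial transcription factors (10 rose and 9 fell). The labels do not say that replicates are separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

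Lung iECs rose above lung fibroblasts in arterial and pan-endothelial genes. Of 19 arterial genes 18 rose and 1 fell (median 2.82; fry adjusted p = 8.03e-12, adjusted p = 0.00815 with an estimated correlation), led after Sox17 by Gja5 at 7.79 ± 0.289, Sema3g at 5.29 ± 0.294 and Dll4 at 5.12 ± 0.238. Of 28 pan-endothelial genes 19 rose and 2 fell (median 2.74; fry adjusted p = 1.64e-11, adjusted p = 0.0429 with an estimated correlation). The sialomucin gene Emcn rose by 8.01 ± 0.154, Cdh5, which encodes VE-cadherin, by 7.18 ± 0.153 and the receptor gene Tie1 by 7.10 ± 0.146, while Cd34 fell by 3.57 ± 0.116. Of 24 endothelial transcription factors 14 rose and 4 fell, with Klf4 at −1.56 ± 0.157 (adjusted p = 0.0508 with an estimated correlation). Of 16 Notch genes 12 rose and 1 fell, among them Jag1 by 2.84 ± 0.135 (adjusted p = 0.0920 with an estimated correlation).

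Fibroblast and matrix genes fell in 27 of 30 cases in lung iECs, among them the microfibril gene Mfap4 by 7.22 ± 0.320, Lum by 4.36 ± 0.420 and Col3a1 by 3.39 ± 0.196, and Postn rose by 0.31 ± 0.0817 (adjusted p = 0.0761 with an estimated correlation). Contractile genes rose in 13 of 15 cases, with Cnn1 at 2.37 ± 0.362 and Acta2 at 2.13 ± 0.185, and Des fell by 2.17 ± 0.291 (adjusted p = 0.295 with an estimated correlation). Mesothelial genes fell in 8 of 10 cases, with Lrrn4 at −5.45 ± 0.429 and Msln at −5.19 ± 0.234 (adjusted p = 0.374 with an estimated correlation). The p53 list rose in 9 of 12 cases by small steps, such as Mdm2 at 0.76 ± 0.0814 (adjusted p = 0.300 with an estimated correlation). Of 20 cell cycle genes 5 rose, with Cdc20 at 1.25 ± 0.129 (adjusted p = 0.625 with an estimated correlation). Macrophage genes rose in 15 of 16 cases, with Itgam at 1.87 ± 0.276 and Ptprc at 1.81 ± 0.202 (adjusted p = 0.0796 with an estimated correlation). The wider macrophage set made up 0.637% ± 0.0376 of counts in lung fibroblasts and 1.25% ± 0.316 in lung iECs (SD, n = 3). Tmprss5 and Havcr1 had no count in lung fibroblasts and stood at 58.9 and 27.3 CPM in lung iECs, at least 1190-fold and 550-fold higher. In all 3850 genes were higher and 3668 lower in lung iECs than in lung fibroblasts, and against a log2 change of 1, 1109 of 1806 calls (61.4%) were higher in iECs. Adjusted over the list alone, 1 further gene rose in the Notch (13) and contractile (14) lists and 1 further gene fell in the fibroblast (28) and p53 (1) lists.

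**Figure D2:**
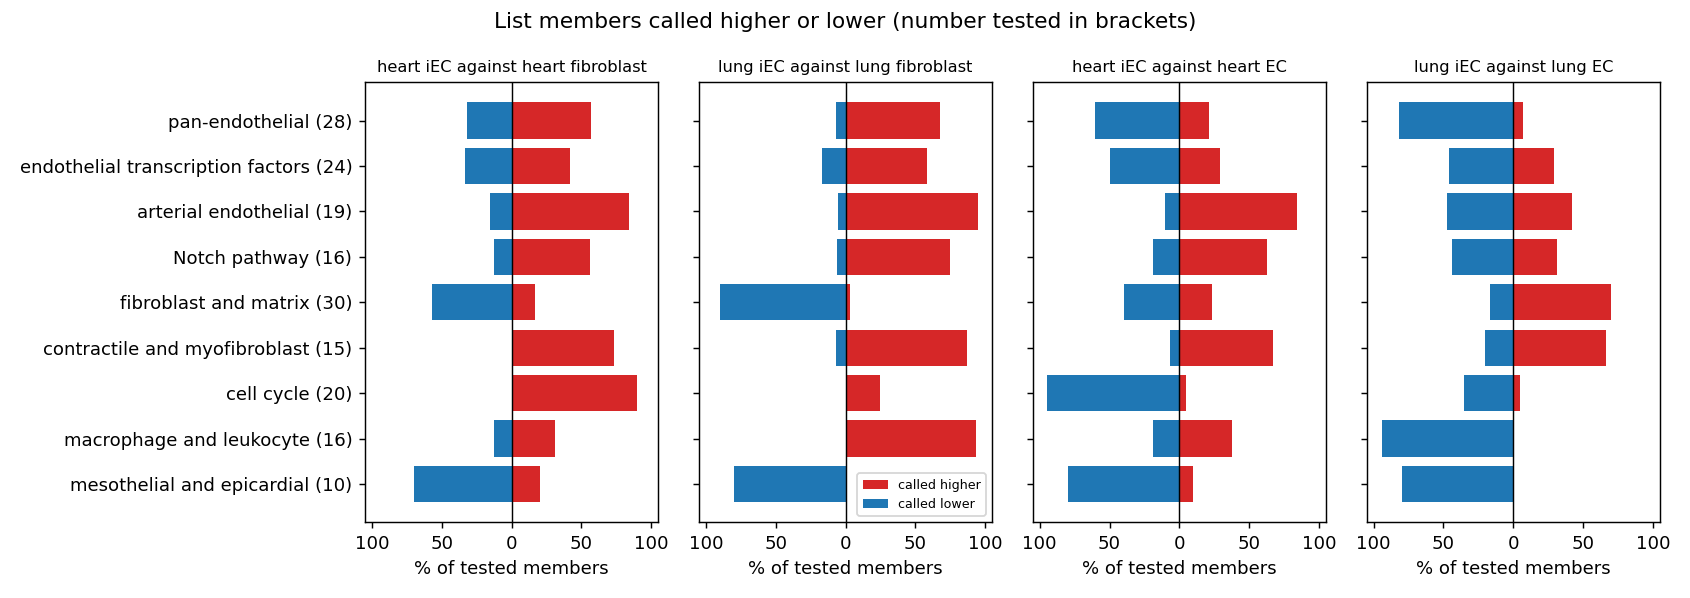
Bars give the percentage of tested members of 9 gene lists called higher (right) or lower (left) in 4 comparisons, with the number tested in brackets. Arterial genes were called higher in 16 of 19 cases in heart iECs and 18 of 19 in lung iECs against fibroblasts, and pan-endothelial genes were called lower in 17 and 23 of 28 cases against native ECs.

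The change from fibroblast to iEC was shared between the organs for many genes, and a test of the difference called 1873 genes with a larger log2 change in the lung and 1871 with a smaller one. Pan-endothelial genes had the larger log2 change in the lung in 21 of 28 cases and the smaller in 1 (median difference 1.83; fry adjusted p = 1.47e-07, adjusted p = 0.0196 with an estimated correlation), with Emcn at 5.82 ± 0.184, Cdh5 at 4.30 ± 0.178 and Tie1 at 4.08 ± 0.184. Their starting levels differed: Cdh5 stood at 75.5 CPM in heart fibroblasts and 3.17 in lung fibroblasts, but at 555 and 465 CPM in the iECs. Of 24 endothelial transcription factors 13 had the larger change in the lung and 4 the smaller, with Erg at 3.88 ± 0.323 and Sox17 at 3.35 ± 0.411 (fry adjusted p = 1.57e-07, adjusted p = 0.0441 with an estimated correlation). Sox17 and Erg stood at nearly the same level in heart and lung iECs, so their differences came from lower starting levels in lung fibroblasts. Cell cycle genes had the smaller log2 change in the lung in 14 of 20 cases, with Mki67 at −2.69 ± 0.226, and the larger in none (adjusted p = 0.236 with an estimated correlation). All 20 were already higher in lung than in heart fibroblasts, and most were also higher in lung than in heart iECs. The macrophage list had 12 of 16 genes with a larger change in the lung, such as Cd68 at 1.58 ± 0.199 (adjusted p = 0.236 with an estimated correlation), and the fibroblast list 17 of 30 with a smaller one and 4 with a larger one, with the crosslinking enzyme gene Lox at −2.21 ± 0.156 (adjusted p = 0.324 with an estimated correlation). Adjusted over the list alone the larger and smaller counts were 24 and 1 for pan-endothelial genes, 14 and 4 for endothelial transcription factors, 13 and 0 for macrophage genes, 6 and 17 for fibroblast genes, and unchanged for the cell cycle. Of the genes that rose in heart iECs 2342 also rose in lung iECs, where independent lists would share 1002, and of those that fell 2235 also fell, against 904 for independent lists. Of those that rose in heart iECs 193 fell in lung iECs, and of those that fell 233 rose. Across all tested genes the changes in the 2 organs correlated at r = 0.64 and rho = 0.594, with genes not independent of each other.

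Heart ECs differed from heart fibroblasts in endothelial genes. Of 28 pan-endothelial genes 27 were higher and 1 lower (median 2.54; fry adjusted p = 3.24e-14, adjusted p = 0.000413 with an estimated correlation), with the clotting factor gene Vwf at 3.79 ± 0.138, Emcn at 3.43 ± 0.111 and the tight junction gene Cldn5 at 3.08 ± 0.207. Endothelial transcription factors were higher in 17 of 24 cases and lower in 2, with Hhex at 3.34 ± 0.268 and Sox7 at 3.05 ± 0.188 (adjusted p = 0.000951 with an estimated correlation). Lymphatic genes were higher in 9 of 10 cases, among them Lyve1 at 2.96 ± 0.128 and the lymphatic regulator Prox1 at 2.46 ± 0.238 (adjusted p = 0.00153 with an estimated correlation). Venous genes were higher in 9 of 12, among them the selectin gene Selp at 4.75 ± 0.609 (adjusted p = 0.0556 with an estimated correlation). Beyond endothelial genes, all 20 cell cycle genes were higher, with Mki67 at 3.66 ± 0.176 (adjusted p = 0.0317 with an estimated correlation). All 10 mesothelial genes were higher as well, with Msln at 2.92 ± 0.199 (adjusted p = 0.154 with an estimated correlation), although the wider mesothelial set held 1.10% ± 0.0596 of counts in heart fibroblasts and 0.776% ± 0.0437 in heart ECs (SD, n = 3). Inflammatory genes were higher in 15 of 17 cases and lower in 1, with the neutrophil chemokine gene Cxcl2 at 7.10 ± 1.49 (fry adjusted p = 0.00741, adjusted p = 0.505 with an estimated correlation). Fibroblast genes were lower in 18 of 30 cases, with Mfap4 at −5.23 ± 0.245 and Pdgfrb at −1.32 ± 0.140 (adjusted p = 0.185 with an estimated correlation). In all 3590 genes were higher and 3461 lower. In heart ECs, adjusted over the list alone, 18 endothelial transcription factors were higher, and of the fibroblast genes 1 was higher and 19 lower. Against a log2 change of 1, 867 of 1175 calls (73.8%) were higher in ECs.

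Lung ECs differed from lung fibroblasts in endothelial, fibroblast and macrophage genes. Of 28 pan-endothelial genes 27 were higher and none lower (median 5.99; fry adjusted p = 3.35e-15, adjusted p = 0.000811 with an estimated correlation), with Mmrn2 at 9.17 ± 0.304, Emcn at 8.87 ± 0.157 and Tie1 at 8.61 ± 0.149. Endothelial transcription factors were higher in 18 of 24 cases, with Sox18 at 8.08 ± 0.234, and lower in 4, with Meox2 at −4.05 ± 0.227 (adjusted p = 0.00654 with an estimated correlation). Lymphatic genes were higher in 8 of 10 cases, with Reln at 9.45 ± 0.263 and Lyve1 at 6.62 ± 0.156 (adjusted p = 0.00654 with an estimated correlation). Venous genes were higher in 9 of 12, with Selp at 9.32 ± 0.801 (adjusted p = 0.112 with an estimated correlation). Fibroblast genes were lower in 27 of 30 cases, with Mfap4 at −7.47 ± 0.325 and Col3a1 at −4.59 ± 0.207 (adjusted p = 0.0237 with an estimated correlation). Lung mesenchyme transcription factors were lower in 14 of 16, with Tbx4 at −1.76 ± 0.141 (adjusted p = 0.00654 with an estimated correlation). Markers of other cell types were higher too: all 16 macrophage genes, with Itgam at 3.64 ± 0.291 and the lysozyme gene Lyz2 at 2.98 ± 0.195 (adjusted p = 0.0167 with an estimated correlation), and 6 of 7 epithelial genes, with Cldn4 at 8.95 ± 0.330 (adjusted p = 0.0259 with an estimated correlation). The wider macrophage set made up 3.29% ± 0.600 of counts in lung ECs (SD, n = 3) and 49 tested epithelial genes 0.0951% ± 0.00172. The inflammatory list, with 13 of 17 genes higher, was not called (fry adjusted p = 0.139). In all 4358 genes were higher and 4271 lower, and adjusted over the list alone the counts of these lists were the same.

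Against native heart ECs, heart iECs had more arterial and less lymphatic transcript. Of 19 arterial genes 16 were higher and 2 lower (median 2.17; fry adjusted p = 4.56e-13, adjusted p = 0.00542 with an estimated correlation), with Gja5 at 6.06 ± 0.224, Hey1 at 5.74 ± 0.298 and the elastic fibre gene Fbln5 at 4.07 ± 0.168, and the chemokine receptor gene Cxcr4 lower at −1.94 ± 0.183. Notch genes were higher in 10 of 16 cases and lower in 3, with Dll4 at 2.72 ± 0.134 and the Notch modifier gene Mfng at −5.49 ± 0.507 (adjusted p = 0.0977 with an estimated correlation). Pan-endothelial genes were lower in 17 of 28 cases, with Plvap, a gene of fenestrated and venous vessels, at −6.30 ± 0.241, Nos3 at −4.96 ± 0.341 and Cldn5 at −4.82 ± 0.236, and higher in 6, with Ptprb at 2.44 ± 0.111 (median −1.20; adjusted p = 0.0508 with an estimated correlation). Lymphatic genes were lower in 8 of 10 cases, with Mmrn1 at −6.27 ± 0.200 (adjusted p = 0.0234 with an estimated correlation). Venous genes were lower in 9 of 12, with Selp at −6.07 ± 0.654 (adjusted p = 0.0508 with an estimated correlation). Capillary genes were lower in 8 of 13, with Gpihbp1 at −6.00 ± 0.313 (adjusted p = 0.0713 with an estimated correlation). Inflammatory genes were lower in 14 of 17 cases, with Lcn2 at −8.27 ± 1.13 (adjusted p = 0.580 with an estimated correlation). Interferon genes were lower in 13 of 16, with Cxcl10 at −4.48 ± 1.06 (adjusted p = 0.586 with an estimated correlation). Mesothelial genes were lower in 8 of 10, with Msln at −8.22 ± 0.289 (adjusted p = 0.373 with an estimated correlation). Cell cycle genes were lower in 19 of 20, with Mcm6 at −1.25 ± 0.103 (adjusted p = 0.135 with an estimated correlation). TGF-beta and BMP genes were higher in 12 of 18 cases, with Bmp4 at 1.59 ± 0.0966 (adjusted p = 0.0430 with an estimated correlation). In all 3639 genes were higher and 3633 lower, and against a log2 change of 1, 691 of 1775 calls (38.9%) were higher in iECs. Of the pan-endothelial genes, adjusted over the list alone, 7 were higher and 18 lower and the other counts were the same.

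Lung iECs were lower than lung ECs in 23 of 28 pan-endothelial genes and higher in 2 (median −2.21; fry adjusted p = 1.10e-13, adjusted p = 0.00289 with an estimated correlation). Plvap differed by −9.18 ± 0.290, Mmrn2 by −8.93 ± 0.295 and Cldn5 by −6.98 ± 0.267, while Kdr was higher at 1.80 ± 0.122. Arterial genes went both ways, with 8 higher, among them Sox17 at 5.06 ± 0.149, and 9 lower, among them Cxcr4 at −3.75 ± 0.187 and Dll4 at −1.85 ± 0.133; the median was −0.12, the mean 0.47 and the fry direction up (adjusted p = 0.819 with an estimated correlation). Notch genes were higher in 5 of 16 cases, with Hey1 at 3.18 ± 0.273, and lower in 7, with Nrarp at −4.63 ± 0.332 (adjusted p = 0.785 with an estimated correlation). Lymphatic genes were lower in 9 of 10 cases, with Mmrn1 at −8.81 ± 0.227 (adjusted p = 0.00373 with an estimated correlation). Venous genes were lower in 10 of 12, with Vwf at −5.70 ± 0.158 (adjusted p = 0.0730 with an estimated correlation). Capillary genes were lower in 8 of 13, with the lipase gene Lpl at −2.17 ± 0.242 (adjusted p = 0.0343 with an estimated correlation). Macrophage genes were lower in 15 of 16 cases, with Lyz2 at −1.52 ± 0.185 (adjusted p = 0.0354 with an estimated correlation). Epithelial genes were lower in 6 of 7, with Krt8 at −6.07 ± 0.285 (adjusted p = 0.0354 with an estimated correlation). Fibroblast genes were higher than in ECs in 21 of 30 cases, with Fap at 2.42 ± 0.275, and lower in 5, with Lum at −2.95 ± 0.454 (adjusted p = 0.242 with an estimated correlation), and lung mesenchyme transcription factors were higher in 11 of 16, with Tcf21 at 1.55 ± 0.177 (adjusted p = 0.00779 with an estimated correlation). Sphkap, a gene of the A-kinase anchoring protein family, had no count in lung ECs and stood at 171 CPM in lung iECs, at least 3950-fold higher. The inflammatory list was not called (2 higher and 6 lower of 17; fry adjusted p = 0.0733). In all 3296 genes were higher and 3419 lower. Adjusted over the list alone 24 pan-endothelial, 16 macrophage and 7 inflammatory genes were lower and 12 mesenchyme factors higher.

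The position of iECs on the axis from fibroblast (0) to native EC (1) was computed over genes that differed at least 2-fold between these groups. Heart iECs stood at 0.452 ± 0.011 over 2375 genes and lung iECs at 0.533 ± 0.051 over 3582 genes (SD, n = 3). The ends of the axis lay closer together in the heart, at a root mean square log2 distance of 1.04 against 1.46 in the lung. Positions in heart and lung are therefore not on a common scale. Over genes lower in ECs and over genes higher in ECs the position was 0.876 ± 0.008 and 0.324 ± 0.017 in the heart and 0.645 ± 0.054 and 0.479 ± 0.051 in the lung. The organ difference of 0.081, between values over different gene sets, gave p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 libraries allow. It was 0.051 without lung iEC replicate 3, 0.048 without the genes of the wider marker lists and 0.044 over the 1348 genes common to both organs. Of the genes higher in heart ECs than in fibroblasts 1896 of 3590 (52.8%) were also higher in heart iECs, against 934 for independent lists, and of those lower 1908 of 3461 (55.1%), against 853; 448 and 325 were called in the opposite direction in iECs. In the lung the counts were 2553 of 4358 (58.6%), against 1129, and 2595 of 4271 (60.8%), against 1054, with 169 and 304 in the opposite direction. These comparisons use the same 3 fibroblast libraries, which are too few to split, so part of the excess may come from them. Simulated unchanged iECs shared 0 genes. They were drawn around the mean of these same fibroblast libraries, so the simulation cannot measure that part.

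**Figure D3:**
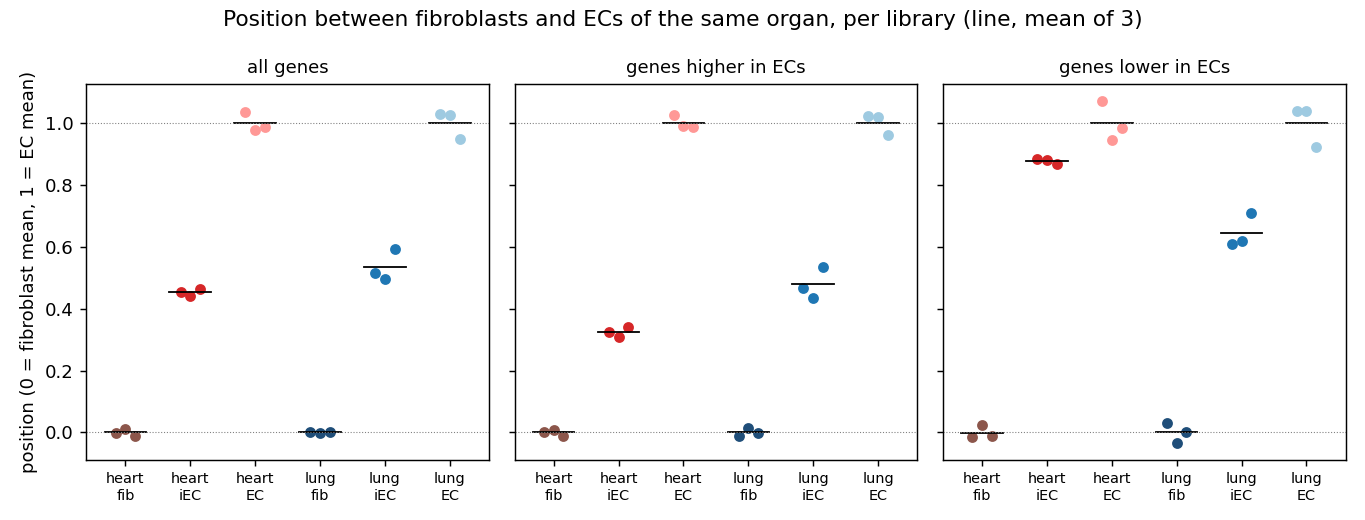
Position of each library between the fibroblast mean (0) and the EC mean (1) of its own organ, over all genes that differed at least 2-fold, over those higher in ECs and over those lower in ECs, with 3 libraries per group and a line at the mean. Heart iECs lie at 0.44 to 0.462 and lung iECs at 0.495 to 0.591 over all these genes.

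Fibroblasts of the lung and the heart differed in the transcription factors that pattern their organs. Of 16 lung mesenchyme factors 15 were higher in lung fibroblasts and 1 lower (median 3.84; fry adjusted p = 2.02e-11, adjusted p = 0.00284 with an estimated correlation), with the homeobox gene Hoxa5 at 6.94 ± 0.278 and Tbx4 at 6.15 ± 0.201, and Tcf21 at −4.19 ± 0.147. Of 9 heart mesenchyme factors 5 were lower, with the cardiac regulator Tbx20 at −8.63 ± 0.162, Hand2 at −3.84 ± 0.103 and Gata4 at −3.72 ± 0.163, and 2 higher, with Wt1 at 3.60 ± 0.258 (adjusted p = 0.319 with an estimated correlation). Pan-endothelial genes were lower in lung fibroblasts in 26 of 28 cases, with Tie1 at −5.22 ± 0.150 and Emcn at −4.96 ± 0.152 (adjusted p = 0.00284 with an estimated correlation). Macrophage genes were higher in 14 of 16 cases, with Ctss at 2.90 ± 0.117 (adjusted p = 0.0491 with an estimated correlation), although the wider macrophage set held 0.703% ± 0.0200 of counts in heart fibroblasts and 0.637% ± 0.0376 in lung fibroblasts. All 20 cell cycle genes were higher, with Mki67 at 4.03 ± 0.177 (adjusted p = 0.0530 with an estimated correlation), as were 13 of 15 contractile genes, with Actg2 at 7.68 ± 0.338 (adjusted p = 0.220 with an estimated correlation), and all 10 mesothelial genes, with Wt1 counted here too (adjusted p = 0.197 with an estimated correlation). The wider mesothelial set again went the other way, with 0.434% ± 0.0684 of counts in lung fibroblasts and 1.10% ± 0.0596 in heart fibroblasts. In all 3658 genes were higher and 3546 lower in the lung, with the same counts adjusted over the list alone.

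The organ pattern of mesenchyme factors stood in iECs as well. Of 16 lung mesenchyme factors 15 were higher in lung iECs than in heart iECs and 1 lower (median 3.65; fry adjusted p = 3.81e-12, adjusted p = 0.000746 with an estimated correlation), with Hoxa5 at 6.20 ± 0.270 and Tbx4 at 4.23 ± 0.170. Tbx20 differed by −7.18 ± 0.153 and Gata4 by −4.30 ± 0.166, with 5 of 9 heart factors lower and 1 higher (adjusted p = 0.123 with an estimated correlation). Arterial genes were lower in lung iECs in 15 of 19 cases and higher in none (median −1.86; fry adjusted p = 3.81e-12, adjusted p = 0.00120 with an estimated correlation), with the kinase gene Bmx at −5.37 ± 0.207, Sema3g at −3.53 ± 0.173 and Dll4 at −3.05 ± 0.136. Notch genes were lower in 12 of 16 cases and higher in 1, with Heyl at −3.69 ± 0.312 (adjusted p = 0.0198 with an estimated correlation). Pan-endothelial genes were lower in 19 of 28, with Pecam1 at −3.75 ± 0.103 and Vwf at −2.57 ± 0.150, against 5 higher, with Esam at 1.67 ± 0.128 (adjusted p = 0.0208 with an estimated correlation). All 16 macrophage genes were higher in lung iECs, with Cd68 at 3.93 ± 0.149 (adjusted p = 0.00706 with an estimated correlation), and the wider set made up 0.270% ± 0.00638 of counts in heart iECs and 1.25% ± 0.316 in lung iECs (SD, n = 3). Cell cycle genes were higher in 19 of 20 cases, with Birc5 at 1.61 ± 0.213 (adjusted p = 0.0559 with an estimated correlation). Contractile genes were higher in 12 of 15, with Cnn1 at 5.61 ± 0.451 (adjusted p = 0.139 with an estimated correlation). Lung endothelial genes were higher in 9 of 18, with Foxf1 at 3.50 ± 0.167, against 4 lower (adjusted p = 0.0845 with an estimated correlation). The heart endothelial list was not called, with 4 of 11 genes higher and 5 lower (fry adjusted p = 0.0537; median −0.54, mean 0.20). Fibroblast genes were lower in 21 of 30 cases, with Mfap4 at −4.45 ± 0.336 (adjusted p = 0.0845 with an estimated correlation). In all 2803 genes were higher and 2804 lower, and against a log2 change of 1, 883 of 1280 calls (69.0%) were higher in the lung. Adjusted over the list alone, 6 heart factors, 20 pan-endothelial and 22 fibroblast genes were lower, and 2 Notch and 3 fibroblast genes higher.

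Native ECs showed the same direction for the mesenchyme factors, with 15 of 16 lung factors higher in lung ECs and 1 lower (adjusted p = 0.0151 with an estimated correlation) and 6 of 9 heart factors lower and 1 higher (adjusted p = 0.123 with an estimated correlation). Tbx4 differed by 5.34 ± 0.224, Tbx20 by −7.14 ± 0.151 and Hand2 by −3.89 ± 0.0972. Pan-endothelial genes were higher in lung ECs in 15 of 28 cases, with Cd93 at 1.54 ± 0.105 and Cdh5 at 1.10 ± 0.112, and lower in 7, with Clec14a at −1.29 ± 0.173 (adjusted p = 0.199 with an estimated correlation). Of 18 lung endothelial genes 9 were higher, with the cytochrome gene Cyp4b1 at 2.04 ± 0.191, and 5 lower, with Scn7a at −4.05 ± 0.354 (adjusted p = 0.488 with an estimated correlation). Of 11 heart endothelial genes 6 were higher in lung ECs, against the name of the list, and 2 lower (median 0.29; fry adjusted p = 3.16e-06, adjusted p = 0.257 with an estimated correlation). Macrophage genes were higher in 15 of 16 cases, with Fcer1g at 5.52 ± 0.221 (adjusted p = 0.0151 with an estimated correlation). Contractile genes were higher in 14 of 15, with Myh11 at 3.02 ± 0.282 (adjusted p = 0.181 with an estimated correlation). Epithelial genes were higher in 6 of 7 (adjusted p = 0.0376 with an estimated correlation). The epithelial genes Cldn4 and Epcam had no count in heart ECs and stood at 60.0 and 17.2 CPM in lung ECs, at least 1170-fold and 335-fold higher. Fibroblast genes were lower in 27 of 30 cases, with Lum at −4.80 ± 0.319 (adjusted p = 0.0376 with an estimated correlation). Cardiomyocyte genes were lower in 6 of 8, with the troponin gene Tnnt2 at −4.60 ± 0.253 (adjusted p = 0.170 with an estimated correlation). The wider macrophage set made up 0.578% ± 0.0314 of counts in heart ECs and 3.29% ± 0.600 in lung ECs. In all 3599 genes were higher and 3524 lower in the lung. With p adjusted over the list alone, 7 heart factors were lower and 16 macrophage genes higher.

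**Figure D4:**
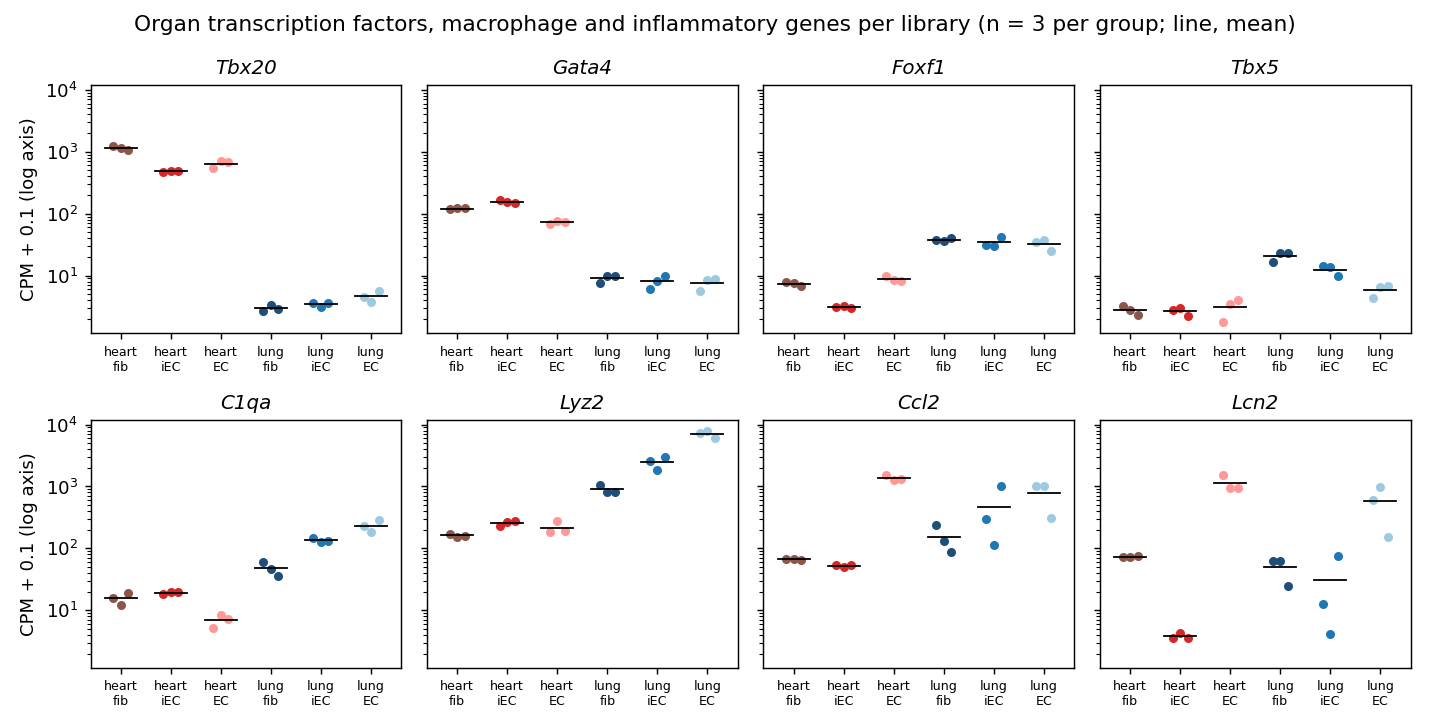
CPM plus 0.1 on a log axis for 4 organ transcription factors, 2 macrophage genes and 2 inflammatory genes in each library, with 3 libraries per group and a line at the mean. Tbx20 lies at 482 to 1143 CPM in the heart group means and at 2.88 to 4.53 in the lung group means; Ccl2 reaches 1000 CPM in 1 lung iEC library.

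The organ genes of native ECs were then sought among iECs and fibroblasts. Of 7123 genes that differed between lung and heart ECs, 3207 (45.0%) differed in the same direction between lung and heart iECs, against 1344 for independent lists, and 514 in the opposite direction. For comparison, 3489 of the 7123 differed in the same direction between lung and heart fibroblasts, against 1726 for independent lists, and 1171 of these were not called in iECs. With ECs tested against a log2 change of 1, the share was 1161 of 1641 (70.7%). Of the 3207, 2210 (68.9%) also differed in that direction between the fibroblasts. Among the genes higher in the lung in all 3 cell types were the macrophage gene Chil3 (10.81 ± 0.324 in ECs, 9.99 ± 0.340 in iECs, 9.41 ± 0.333 in fibroblasts) and Mcemp1, and among those higher in the heart were Dpep1 (−7.45 ± 0.196 in ECs, −2.63 ± 0.147 in iECs, −2.54 ± 0.145 in fibroblasts) and Abca8a (−7.29 ± 0.453, −3.39 ± 0.311 and −2.71 ± 0.301). In fibroblasts 221 of the 3207 were called in the opposite direction, 99 of them higher in the lung in ECs and iECs and 122 higher in the heart. The remaining 776 were called in ECs and iECs and not in fibroblasts, 420 higher in the lung and 356 in the heart. Those higher in the lung included Wfdc21 and the interleukin gene Il1a, at 132.5 ± 96.1 CPM in lung ECs, 42.4 ± 52.2 in lung iECs (SD, n = 3), 1.52 in heart ECs and 0.129 in heart iECs. In lung and heart fibroblasts Il1a stood at 4.09 and 0.0377 CPM and Wfdc21 at 1.03 and 0.142. Il1a varied between lung libraries, at 20.3, 4.90 and 102 CPM in iEC replicates 1 to 3 and 193, 183 and 21.7 in the ECs, as Cxcl5 did (13.2, 6.83 and 175; 97.1, 135 and 6.67). DESeq2 called Il1a and Wfdc21 higher in lung than in heart fibroblasts too. Those higher in the heart included the protease inhibitor gene Serpina3m (−6.42 ± 0.245 in ECs, −2.52 ± 0.465 in iECs, −0.23 ± 0.165 in fibroblasts), Igfbp5 (−4.98 ± 0.418, −1.72 ± 0.342 and 0.61 ± 0.314) and the growth factor gene Vegfd (−4.46 ± 0.444, −1.38 ± 0.395 and −0.02 ± 0.366). That a gene was not called in fibroblasts does not show that its organ difference arose in iECs.

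Markers of macrophages were common among the shared genes: 153 of the 1115 genes higher in the lung in all 3 cell types (13.7%) were on the wider macrophage list, against 46 of the other 2484 genes higher in lung ECs (1.85%; odds ratio 8.42, two-sided Fisher's exact test, adjusted p = 6.03e-42 over 18 tests). Among the 420 genes gained in the lung the share was 8.33%, against 5.16% (adjusted p = 0.0714). The 5.16% covers all other genes higher in lung ECs, the shared ones included. Fisher's test takes genes as independent, but markers of a cell type can move together. Its p-values therefore do not measure the spread between libraries and may overstate the evidence. Of the 1707 genes higher in lung ECs and not called in iECs, 7 (0.41%) were on the list. Leaving out the genes of the wider macrophage, mesothelial and epithelial lists, an alternative chosen after the data were seen, gave 2992 of 6848 shared genes (43.7%). Across all 14864 genes the lung to heart log2 differences of iECs correlated with those of ECs at r = 0.575 (rho = 0.468) and with those of fibroblasts at r = 0.574 (rho = 0.506), and those of fibroblasts with ECs at r = 0.483 (rho = 0.409). In exact permutation tests over the 10 splits of 6 libraries each gave p = 0.1 (two-sided), the smallest possible, and the adjusted values over these 3 relations were also 0.1. The change of the organ difference from fibroblasts to iECs correlated with the EC difference at r = 0.0596 (rho = −0.00492), and given the fibroblast difference the partial correlation of iECs with ECs was 0.415. These are correlations across genes, which are not independent replicates.

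The lung to heart difference was also compared between iECs and ECs. It lay further toward the lung in iECs for 2049 genes and further toward the heart for 1815. Arterial genes shifted toward the heart in 12 of 19 cases and toward the lung in 2 (median −1.74; fry adjusted p = 6.92e-10, adjusted p = 0.00295 with an estimated correlation), with Dll4 at −4.57 ± 0.189, Sema3g at −4.29 ± 0.239 and Jag2 at −3.79 ± 0.440, as did 21 of 28 pan-endothelial genes against 2 (median −2.03; adjusted p = 0.00295 with an estimated correlation), with Pecam1 at −4.61 ± 0.134. Pecam1 stood at 96.3 CPM in heart iECs and 7.13 in lung iECs, but at 310 in heart ECs and 562 in lung ECs. Notch genes shifted toward the heart in 11 of 16 cases and toward the lung in 1, with Hey1 at −2.57 ± 0.409 and Dll1 at 2.67 ± 0.398 (adjusted p = 0.0242 with an estimated correlation). Fibroblast genes shifted toward the lung in 18 of 30 cases, with Col6a1 at 2.85 ± 0.180, and toward the heart in 3 (adjusted p = 0.126 with an estimated correlation), and macrophage genes toward the heart in 13 of 16, with C1qa at −2.27 ± 0.312, and toward the lung in 1 (adjusted p = 0.0604 with an estimated correlation). The counts, adjusted over the list alone, toward the heart and the lung were 14 and 2 for arterial genes, 21 and 3 for pan-endothelial genes, 12 and 2 for Notch genes, 3 and 19 for fibroblast genes and 14 and 1 for macrophage genes.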

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

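The tests of endothelial transcripts in heart fibroblasts, of macrophage transcripts and of arterial genes, with the limits that decide them, were chosen after the results were seen; the splits of the libraries were planned. The selection of lists and genes listed here was also set after the results were seen: lists called for a difference between organs by fry and with an estimated correlation, and named genes called in opposite directions in the organs.

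The iEC response differed between organs for 3744 genes, and the lung to heart difference differed between iECs and ECs for 3864 genes. For the response the median log2 difference, lung minus heart, was 1.83 in pan-endothelial genes and 0.95 in endothelial transcription factors. For the organ difference, iECs minus ECs, it was −2.03 in pan-endothelial, −1.74 in arterial, −0.78 in lymphatic, −0.99 in angiogenic tip cell, −1.48 in Notch and −0.50 in TGF-beta and BMP genes. In all 426 genes responded in opposite directions with a called difference, 233 that rose in the lung and fell in the heart and 193 the other way, to which both genes named here belong. Map3k7cl rose in heart iECs and fell in lung iECs (difference −5.40 ± 0.658; 0.215 and 2.99 CPM in heart fibroblasts and iECs, 10.35 and 3.25 in lung fibroblasts and iECs). Cxadr, the gene of a junctional virus receptor, did likewise (difference −4.22 ± 0.376; 7.26 and 16.9 CPM, 69.45 and 8.68 CPM).

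Of 100 drawn splits of the 12 libraries into 4 groups of 3, 2, the real one included, called as many genes as the 3744 of the response (highest other 4831), and 4, the real one included, as many as the 3864 of the organ difference (highest other 5419). These draws also break up the cell type and organ effects, so they are no fair null for an interaction and do not show whether these counts exceed chance. For gene lists, 1 of 50 drawn splits of the 18 libraries, the real one, gave as many list calls (242 real, highest other 14). These draws too break up all cell type and organ effects, so they ask only whether the groups differ at all. They test no single list. For each comparison of a pair of groups only 10 splits exist, too few for a share under 0.05, and 1 of the 10, the real one, was the largest. The real and highest other counts were 7530 and 0 for heart iECs against fibroblasts, 7518 and 1 for lung iECs against fibroblasts, 7051 and 0 for heart ECs against fibroblasts, 8629 and 0 for lung ECs against fibroblasts, 7272 and 0 for heart iECs against ECs, 6715 and 735 for lung iECs against ECs, 7204 and 0 for fibroblasts between organs, 5607 and 0 for iECs and 7123 and 1 for ECs. The 735 came from the split that puts lung EC replicates 1 and 2 with lung iEC replicate 3. For the overlap of organ genes 1 of 10 splits of the 6 iEC libraries, the real one, was as large (3207 real, highest other 0), again too few splits.

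The larger pan-endothelial response in the lung goes with endothelial transcripts in heart fibroblasts, such as Cdh5 at 75.5 CPM against 3.17 in lung fibroblasts. Mixing of heart EC RNA or reads into the heart fibroblast libraries would carry inflammatory transcripts too, but 5 of 14 inflammatory genes with at least 50 CPM in heart ECs, such as Cxcl2 at 0.00712 of its EC level, lay below 0.5 of the median pan-endothelial ratio of 0.162 in every heart fibroblast library. That value meets its limit of 5 with no margin. Endothelial cells living in the heart fibroblast cultures remain possible: 78.9% of 19 pan-endothelial genes (15) lay within a factor of 2 of the median ratio, just under the 80% set as a limit, and their ratios ranged from 0.0723 to 0.69. A biological difference between heart and lung fibroblasts was not tested and stays open.

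Most genes of the macrophage list were higher in lung than in heart libraries of every cell type, but the wider macrophage set held 0.637% of counts in lung fibroblasts and 0.703% in heart fibroblasts. Macrophages carried in the lung cultures in different shares could account for the list: of 15 macrophage genes, 14 kept the ratio of lung iECs to lung ECs (median 0.454) and 12 that of lung fibroblasts to lung ECs (median 0.171) within a factor of 2, the lower share being 80%, exactly at its limit. Lyz2 stood at 0.348 and Ctss at 0.561 of their lung EC level in lung iECs, and 12 of the 15 genes reached 5 CPM in a heart group, so they are not absent from heart cultures. Leaving out the wider lists does not show whether other cells cause the organ overlap: 308 genes are too few to undo it, so the remaining 2.34 times that of independent lists in the heart direction and 2.41 in the lung direction were bound to stay high. A biological difference in the lung cells themselves was not tested.

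Arterial genes were higher in heart iECs than in heart ECs. Dilution of the heart EC cultures by other cells would lower pan-endothelial genes in the ECs alike. Yet 17 of 28 pan-endothelial genes were lower in heart iECs, with a median of −1.20. Dilution alone would not give both results if iECs otherwise held native levels. In the lung, however, most pan-endothelial genes were also lower in iECs than in ECs. The values therefore do not show how pure the heart EC cultures were, and a part played by dilution stays open. The high levels of Sox17 and Erg, or the conversion itself, stay open as biological explanations and were not tested.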

How the results depend on the processing

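The alternatives without the wider marker lists, and the position over genes changed at least 2-fold in the same direction in both organs, were chosen after the results were seen. Counts of called genes stayed within 1.5 times the reported ones under DESeq2, RLE scaling, no filter, the CPM filter, fits to the compared groups and each library left out. Tested against a log2 change of 1, they were 1876 and 1806 for iECs against fibroblasts in heart and lung, 1175 and 2412 for ECs against fibroblasts, 1775 and 1394 for iECs against ECs, 1666, 1280 and 1641 between organs for fibroblasts, iECs and ECs, 592 for the response and 714 for the organ difference, and 1161 of 1641 organ genes of ECs were shared (70.7%, against 45.0%); this test asks for larger changes, so fewer genes pass by construction, but the shared proportion was higher. Fry made 242 list calls, and camera made 61 with an estimated correlation and 144 with a preset correlation of 0.01. Camera sets a list against the other genes and fry does not, so the drop is not the effect of correlation alone. Of 101 pairs of a list and a comparison set side by side, the call was lost in 56 with the estimated correlation and in 10 with the preset one, and 3 gained one. The position of heart iECs moved from 0.452 to 0.475 over all genes, 0.494 without the wider lists, 0.465 over genes common to both organs and 0.44 to 0.471 with 1 library left out. The lung position moved from 0.533 to 0.546 over all genes, 0.542 without the wider lists, 0.509 over genes common to both organs and 0.503 to 0.55 with 1 library left out. The organ difference of 0.081 was thus 0.044 over the 1348 common genes and 0.048 without the wider lists. It was 0.051 without lung iEC replicate 3 and 0.056 without lung EC replicate 3.

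The correlation of organ differences between iECs and ECs was 0.696 over genes called in ECs, 0.647 with at least 5 CPM, 0.621 with a prior count of 5, 0.529 without the wider lists and 0.537 to 0.564 with 1 library left out. Between iECs and fibroblasts it was 0.692, 0.661, 0.611, 0.548 and 0.536 to 0.559, and between fibroblasts and ECs 0.614 over genes called in ECs, 0.553 with at least 5 CPM, 0.451 without the wider lists and 0.438 to 0.482 with 1 library left out. The cause was not tested. No direction was reversed among these. Of 1347 called pairs of a gene and a comparison, 4 lost their call under DESeq2, 4 under RLE and 22 with a block for the replicate number. With 1 library left out 397 of 9480 values lost their call, in 111 of these pairs. DESeq2 called Il1a and Wfdc21 higher in lung than in heart fibroblasts, so for this pair the absence of a fibroblast call depends on the tool. Depth limits fold changes of genes with no count in a group to lower bounds.

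With a block for the replicate number the counts were 7387, 7354, 6850, 8473, 7092, 6508, 6998, 5378 and 6922 for the 9 comparisons of a pair of groups in the same order, 3551 for the response and 3638 for the organ difference, and 1 list call was lost (interferon genes in heart iECs against fibroblasts, adjusted p = 0.051). The replicate numbers pair no libraries that vary together: in 0 of 15 pairs of groups did all correlations exceed 0.1, they ranged from −0.398 to 0.117, and 5 of 18 libraries matched best with their own number.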

Other observations

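The gene lists and their tests were planned; which lists, genes and libraries to describe here was chosen after the results were seen. Genes of liver sinusoidal endothelium, a vessel type that clears waste, were lower in iECs than in native ECs of both organs. Of 9 tested, 6 were lower and 1 higher in heart iECs, with the scavenger receptor gene Stab1 at −5.06 ± 0.270 and Rspo3 at −4.14 ± 0.154 (adjusted p = 0.0224 with an estimated correlation), and 7 lower in lung iECs, with Lyve1 at −4.79 ± 0.138 and Stab2 at −4.07 ± 0.495 (adjusted p = 0.00544 with an estimated correlation). Angiogenic tip cell genes, which mark sprouting vessels, were higher in lung ECs than in lung fibroblasts in 11 of 16 cases and lower in 4, with Pdgfb at 8.38 ± 0.172 and Angpt2 at 6.68 ± 0.167, and lower in lung iECs than in lung ECs in 12 of 16 cases and higher in 3, with Apln at −4.90 ± 0.120 and Esm1 at −3.84 ± 0.197 (adjusted p = 0.0167 and 0.0105 with an estimated correlation).

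Basement membrane genes were lower in lung iECs than in heart iECs in 12 of 14 cases and higher in none, with Col15a1 at −1.66 ± 0.204 and the laminin gene Lamb2 at −1.06 ± 0.107 (adjusted p = 0.0451 with an estimated correlation). Glycolysis genes were lower in lung iECs than in lung ECs in 11 of 14 cases, with the hexokinase genes Hk1 at −0.85 ± 0.0808 and Hk2 at −0.71 ± 0.146 (adjusted p = 0.517 with an estimated correlation). Adjusted over the list alone the counts were 13 for basement membrane, 12 for glycolysis and unchanged for the liver sinusoidal and tip cell genes named here. Sphkap stood at 161 CPM in heart iECs and 171 in lung iECs and at 0.130 or less in the other groups, and Magix at 78.2 and 24.4 CPM against 0.189 or less.

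Some libraries of the lung stood apart in inflammatory genes. The chemokine gene Ccl2 stood at 1000 CPM in lung iEC replicate 3 and at 293 and 115 in the other lung iEC libraries, and at 308 CPM in lung EC replicate 3 and about 1030 in the other lung EC libraries. Lcn2 stood at 74.6 CPM in lung iEC replicate 3 against 12.8 and 4.13, and at 151 CPM in lung EC replicate 3 against 595 and 990. The position of lung iEC replicate 3 was 0.591, against 0.514 and 0.495. That of lung EC replicate 3 was 0.947, against 1.027 and 1.026, so each of these libraries lay nearer the other group. The split that exchanged these libraries between lung ECs and lung iECs called 735 genes, more than the inflammatory list holds. How many of them belong to an inflammatory response was not examined. Groups of 3 libraries were not tested for outliers.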
